A study of Drosophila melanogaster with 33 samples.

How the data were processed

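RNA editing levels were examined in heads of Drosophila melanogaster, in nascent RNA, which is RNA still attached to chromatin as it is transcribed, and in polyadenylated mRNA. The series holds 33 libraries. Nascent RNA of yw flies was sampled at 6 times of a light:dark cycle in duplicate, which gives 12 libraries. Nascent RNA of males was sampled in 2 libraries each of yw, FM7a and ADAR0 flies, from 40 to 45 heads per the labels. The mRNA libraries comprise 2 of yw and 12 of Canton S flies, and 1 library holds genomic DNA of yw flies. The 12 Canton S libraries cover 6 times, each with 1 library titled PE and 1 titled SE.

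The deposited table lists 1350 sites. Its editing levels are fractions of reads that carry the edited base, and per the file headers the libraries were pooled before the level was taken. There is 1 level for the 6 nascent libraries of replicate set 1, 1 for the 6 of set 2, 1 for all 12, and 1 each for yw mRNA, Canton S mRNA, yw males, FM7a males and ADAR0 males. The authors rounded these fractions to hundredths, and they were multiplied by 100 here to give percent. A further deposited fraction is the 5th percentile of the level over the 12 nascent libraries. The coverage of each site in genomic DNA is a deposited read count, and per the file headers a Yes marks sites seen in all 4 yw and FM7a male libraries. Per the submitters' processing notes the genome build was dm3 and the tools included TopHat, CASAVA 1.6 and, for the male libraries, CASAVA 1.8. How sites were called, and why 1093 sites carry no mRNA level, is not given in the sources used here. Positions are printed as deposited, and whether they count from 0 or 1 is not stated.

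The read depth behind an RNA level is unknown. No confidence interval or detection limit could therefore be given for a level, and a level of 0 means only that the site is listed at 0. Per the labels, all nascent RNA was depleted of polyadenylated RNA. The replicate sets of nascent RNA gave the sole measure of replicate error. The sets also differed in preparation, since the labels describe rRNA depletion for set 1, so their spread holds this difference too. Male and mRNA replicates were pooled in the deposited values and carry no replicate error.

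The design fixed before the data were examined called for values and numbers of sites higher or lower, with no test, where only pooled levels exist. This covered nascent RNA against mRNA, ADAR0 against FM7a, and yw against FM7a. Editing by time of day was not analysed here, because the levels are pooled over times. The mRNA level of a site is the unweighted mean of the yw and Canton S levels, a choice made after the structure of the table was seen, and both strains are also given. Intervals of medians are 95% percentile intervals over 10000 resamples of genes. They describe the spread over genes, not over libraries.

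Exonic and intronic levels were compared by a two-sided permutation test of the Kruskal-Wallis statistic with 100000 permutations, in which all sites of a gene moved together. A first run used the difference of mean log2 levels. It was replaced by the planned rank statistic, and the log2 statistic is kept as an alternative. Of the 9 gene lists fixed in advance, the 5 with 5 or more genes among the edited genes were compared with random draws of as many edited genes, by a two-sided permutation test with 10000 draws. Each list was tested for its median level and for its number of sites per gene, with Benjamini-Hochberg adjustment over the 5 lists for each measure. The background is genes with at least 1 listed site, so these tests say nothing about unedited genes.

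The tests were run on simulated levels placed on the real genes, 200 times each. These levels were log-normal, with spreads within and between genes that were assumed and not fitted to the data. Fewer permutations were used than in the real tests. The rates are therefore only a guide to the real tests. With no difference, the rank test of exons against introns called 4.5% of simulations, and with a 1.5-fold difference it called 100%. With a 1.5-fold shift the list test of levels called 18.5% of simulations for voltage-gated channels, 31.5% for ligand-gated receptors, 27.5% for phototransduction, 20.5% for ATPases and ion pumps and 59.5% for synaptic vesicle release. With no shift it called 0%, 0.5%, 4.5%, 2% and 1.5%.

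Sites and genes were named by a rule fixed before the data were examined. It takes the 10 genes with the most sites, the 5 largest differences between mRNA and nascent RNA in each direction, the 5 highest levels in nascent RNA, in mRNA and in ADAR0, all sites of lists with 4 or fewer edited genes, the 3 genes with the most sites in other lists, and Adar. Ties went by gene name and then position. Its coverage minimum could not be applied. Gene names are those of the table. For entries without a symbol, and to match list names, current symbols were taken from the RefSeq gene table of the Release 6 assembly, which matched 382 of 395 gene entries. Alternatives covered the weighting of genes, replicate sets, mRNA strain, ratio against difference, the male control strain, and subsets of sites. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.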

Results

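Editing levels were available for 1350 sites in 395 gene entries, 12 of which join overlapping genes. Exons held 621 sites in 254 entries and introns held 729 sites in 199 entries. Each level is the share of reads with the edited base, pooled over libraries, and the RNA read depth is unknown. Genomic DNA of the yw strain covered each site with 15 to 112 reads, with a median of 44.

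The 2 replicate sets of nascent RNA, each pooled from 6 libraries, gave levels that correlated across sites with a Pearson's r of 0.951 and a Spearman's rho of 0.917. Sites are not independent replicates. The median absolute difference between the sets was 4 percentage points, the SD of a level from the paired sets was 4.61 points, and 149 sites differed by more than 10 points. No replicate error was available for the mRNA and male levels.

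The genes with the most sites included several ion channel genes. The voltage-gated potassium channel gene Sh had 58 sites, and the sodium channel gene para had 46. The calcium channel gene cac had 26 sites and the diacylglycerol kinase gene rdgA also had 26. CG17684 had 31 sites, CaMKII 29, the synaptic release factor gene unc-13 24, CG42540 23, the channel gene NaCP60E 21 and CG40263 20. These 10 genes held 304 sites, or 22.5% of the total, and 224 of the 304 were intronic. In contrast, 208 gene entries had 1 site each.

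**Figure D1:**
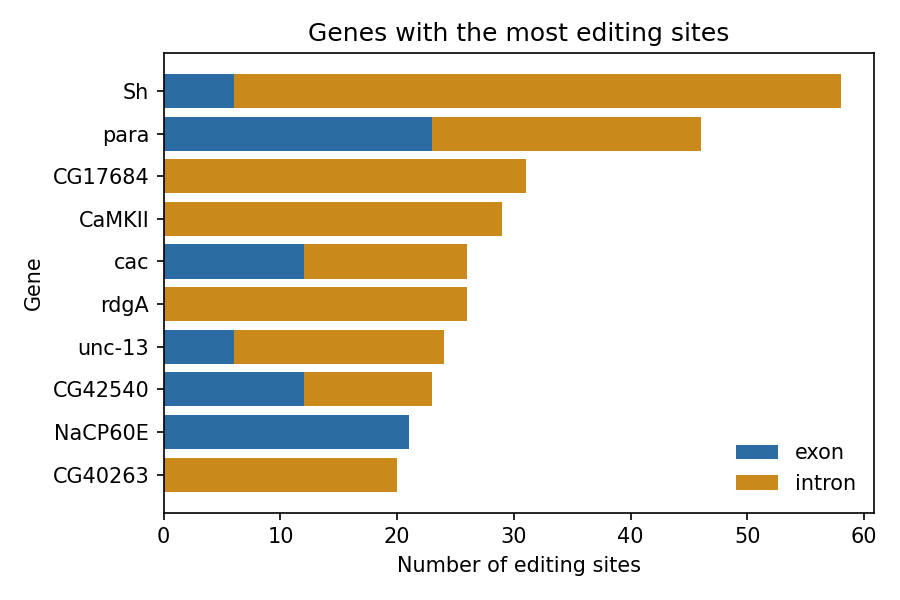
Number of editing sites (horizontal axis) in the 10 genes with the most sites (vertical axis), with exonic and intronic sites stacked. Sh carried 52 intronic and 6 exonic sites, whereas the 21 sites of NaCP60E were all exonic.

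The 14 edited genes of the voltage-gated channel list held 237 sites, or 16.93 per gene against 3.42 over all edited genes (permutation test, adjusted p = 0.001, unadjusted p = 0.0002, the smallest the draws can give). Without Sh the list had 13.77 sites per gene. Gene length was not taken into account. The other 4 lists tested did not pass for sites per gene, with 6.7 for ligand-gated receptors (adjusted p = 0.22 by permutation), 6.17 for synaptic vesicle release (adjusted p = 0.22), 6.2 for ATPases and ion pumps (adjusted p = 0.25) and 6.8 for phototransduction (adjusted p = 0.24).

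No list passed the test for its nascent level after adjustment. In simulation with assumed spreads of levels, the unadjusted test found a 1.5-fold shift in 18.5% to 31.5% of runs for 4 of the lists. For synaptic vesicle release it did so in 59.5%. The median level was 23% for voltage-gated channels (adjusted p = 0.95 by permutation), 36% for ligand-gated receptors (adjusted p = 0.22, unadjusted p = 0.044), 21% for synaptic vesicle release (adjusted p = 1), 19% for ATPases and ion pumps (adjusted p = 0.95) and 14% for phototransduction (adjusted p = 0.47). Among receptor genes, the nicotinic acetylcholine receptor subunit genes nAcRalpha-30D, nAcRalpha-34E and nAcRalpha-80B had 17, 14 and 9 sites with median levels of 49%, 35% and 30%. Among release genes, unc-13, Caps and Snap25 had median levels of 17%, 12% and 19% over 24, 12 and 11 sites. The calcium pump gene PMCA had 19 sites with a median of 19%, the exchanger gene Calx had 5 with 29%, and nrv3 had 4 with 11.5%. Of the phototransduction genes, rdgA had a median of 18%, norpA 10% over 3 sites and rdgB 12% over 2 sites. In ADAR0 males 1 norpA site was at 100% and may not be an edited site. The ADAR0 median was 2.5% for rdgB and 0% for rdgA.

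The circadian clock list was represented by tim alone, with exonic sites at 30% and 15% (chromosome 2L, positions 3503636 and 3503650). Of the muscle list, bt had a site at 31%, Mhc at 29%, Zasp52 at 25% and sls at 10%. The glia and fat body lists had 0 sites. Adar, which encodes the editing enzyme, had 1 exonic site at 24% in nascent RNA (chromosome X, position 1675873), at 26% in yw males, 25% in FM7a males and 0% in ADAR0 males.

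Nascent levels ranged from 4% to 95% with a median of 21%, and 201 sites were at 50% or more. The highest were an exonic site of the calcium channel gene Ca-alpha1D at 95% (chromosome 2L, position 16174194) and an exonic site of Syn, which encodes synapsin, at 95% (chromosome 3R, position 6021148). They were followed by slo at 94% (chromosome 3R, position 20532273), Rya-r44F at 93% (chromosome 2R, position 4771211) and an intronic site of Snap25 at 93% (chromosome 3L, position 24068086). Exonic sites had a median of 27% and intronic sites 18%, a difference of 9 points (permutation test over genes, p = 1e-05, the smallest the permutations can give). When the 257 exonic sites with an mRNA level were left out, an alternative chosen after seeing the data, the difference was -2 points (p = 0.13 by permutation). Those 257 sites had a median of 48%, so leaving them out removes highly edited exonic sites alone.

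How much of the editing in mRNA is already present in nascent RNA could be compared at the 257 sites with an mRNA level, which were all exonic and lay in 128 gene entries. Their nascent median was 48%, against 16% at the 364 exonic sites without an mRNA level. The comparison therefore covers the more highly edited part of the exonic sites. The mRNA level was higher than the nascent level at 186 sites, lower at 65 and equal at 6. The median difference was 5 points (95% interval over resampled genes 3 to 7), and nascent levels were 90.7% of mRNA levels in the median (86.6% to 94.3%). The median was 8 points against the yw mRNA pool and 3 points against the Canton S pool. These pools differ in strain and also in number of libraries, 2 against 12, and in sampling times. The 12 Canton S libraries cover only 6 times, each titled once PE and once SE. Both mRNA pools lay above both nascent sets at 101 sites (39.3%) and below both at 23 sites (8.9%). These counts carry no test. Chance ordering would give 16.7% each only if all levels had the same spread and no ties. The SD of a level was 9.71 points between the mRNA pools and 4.94 points between the nascent sets at these sites.

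**Figure D2:**
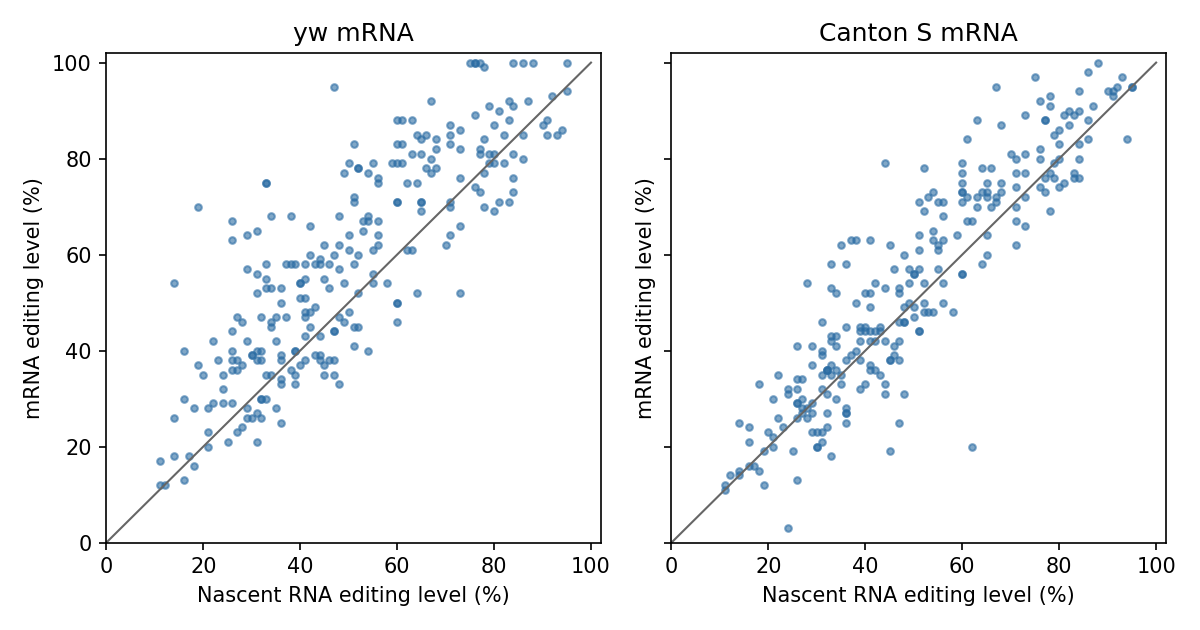
Editing level in mRNA (vertical axis, percent) against nascent RNA (horizontal axis, percent) at 257 exonic sites, for yw mRNA on the left and Canton S mRNA on the right. Each point is a site and the line marks equal levels, with 177 sites above it for yw and 159 for Canton S.

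The largest excess of mRNA was at CG34357 (chromosome 3R, position 319616), with 33% in nascent RNA and 66.5% in mRNA. It was followed by the lipid kinase gene PI4KIIIalpha with 38% and 65.5% (chromosome X, position 2522899) and Ca-alpha1D with 67% and 93.5% (chromosome 2L, position 16174152). Next came fry with 26% and 52% (chromosome 3L, position 9662076) and Lrch with 52% and 78% (chromosome 2L, position 17371342), with a site of unc-13 at the same difference. In the other direction, the phosphodiesterase gene Pde1c had 62% in nascent RNA and 47.5% in mRNA (chromosome 2L, position 11830365), a mean of 75% in yw and 20% in Canton S. The entry CG14425/CG18350 had 73% and 59% (chromosome X, position 6979849) and CG9485 had 47% and 34.5% (chromosome 2R, position 17203191). At CG9485 the nascent sets were at 59% and 43%, yw mRNA at 44% and Canton S mRNA at 25%, so yw mRNA lay above set 2. Next were nAcRalpha-34E with 84% and 74.5% (chromosome 2L, position 14083516) and CG10077 with 33% and 24% (chromosome 3L, position 6943212). The highest mRNA levels were 100% at Ca-alpha1D (position 16174138), 99% at the exchanger gene Nckx30C (chromosome 2L, position 9733349), 98.5% and 97.5% at Ca-alpha1D (positions 16174153 and 16174194) and 97% at nAcRalpha-34E (position 14089246). Nascent levels at these sites were 88%, 86%, 75%, 95% and 84%. Nascent RNA of males did not match all of them. At the first 4, yw males were at 86%, 85%, 13% and 100% and FM7a males at 78%, 79%, 0% and 100%. The nAcRalpha-34E site was listed at 0 in yw males and had no FM7a level. At the 5 largest mRNA excesses, yw males were at 27%, 41%, 20%, 30% and 41% and FM7a males at 46%, 35%, 15%, 11% and 63%.

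By list, mRNA was higher at 38 and lower at 22 of 63 voltage-gated channel sites, with a median difference of 2.5 points. It was higher at 16 of 22 ligand-gated receptor sites, 20 of 25 synaptic release sites and 5 of 5 ATPase and pump sites. At Sh the mean of the mRNA pools was higher at 0 of 4 sites, but yw mRNA alone was higher at 1 and Canton S mRNA alone at 2. At cac the mean was higher at 7 of 7 sites, yw mRNA at 6 and Canton S mRNA at 5. Other genes of the voltage-gated list lay between or at these ends. The mean was higher at 4 of 11 sites of NaCP60E, 3 of 5 of para, 0 of 4 of Ca-alpha1T and 1 of 4 of slo. It was higher at 7 of 7 sites of Shab, 5 of 6 of Ca-alpha1D and 4 of 7 of qvr. At NaCP60E each pool taken alone was higher at most sites, yw mRNA at 7 and Canton S mRNA at 6 of 11, so the mean hides their direction. At para yw mRNA alone was higher at 2 of 5 sites and Canton S mRNA alone at 3. Differences between lists were not tested.

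ADAR0 flies lack the editing enzyme and serve as the background control. Of 1341 sites with an ADAR0 level, 1181 (88.1%) were listed at 0 and 1262 were at 2% or less. At the 1333 sites with both levels, ADAR0 was below FM7a at 1061, above at 32 and equal at 240, of which 229 were at 0 in both. The median difference was -11 points. No test was possible from the pooled levels, and 2 libraries against 2 cannot give an exact two-sided p under 0.33.

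**Figure D3:**
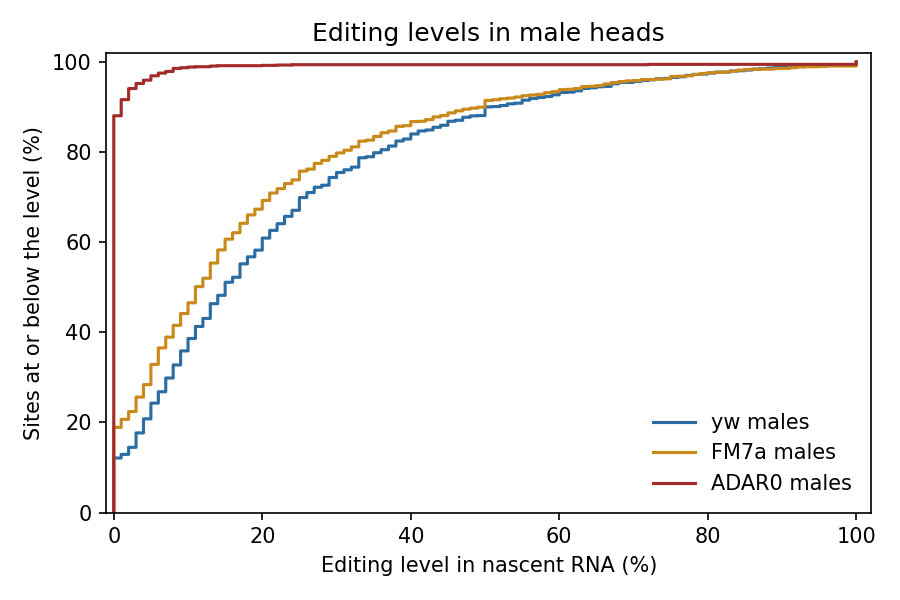
Cumulative share of sites (vertical axis, percent) at or below each editing level (horizontal axis, percent) in nascent RNA of yw, FM7a and ADAR0 male heads. The medians were 15%, 11% and 0%.

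ADAR0 levels were 50% or more at 8 sites. The 5 taken by the rule were all listed at 100% in ADAR0: exonic sites of Atet, CG15431 and CG16791 and intronic sites of CG42784 and dysc. In FM7a they were at 100%, 100%, 100%, 100% and 95%, and in yw males at 1%, 4%, 26%, 0% and 27%. Their positions are 4343232, 4407782 and 13471520 on chromosome 2L for Atet, CG15431 and CG42784, 17147687 on chromosome 3R for CG16791, and 13875879 on chromosome 3L for dysc.

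The yw and FM7a males, which both carry ADAR, were compared beside the ADAR0 contrast. The yw level was higher at 774 of 1336 sites, lower at 426 and equal at 136, with a median difference of 2 points (95% interval over resampled genes 2 to 3). Levels are whole percents, and the lower bound was under 2 in 18 of 20 further draws, with a lowest value of 1. The median absolute difference was 6.5 points. The difference was not tested, as each strain has 1 pooled level, and no replicate spread of the male levels was available to set it against. Of the exonic sites, 374 of 621 (60.2%) were seen in all 4 control male libraries, and of the intronic sites 235 of 729 (32.2%), a difference that was not tested. Intronic sites also had lower male levels, with medians of 13% against 20% in yw and 9% against 15% in FM7a. A site of low level is easier to miss and the read depth is unknown, so the shares do not show that intronic editing is less reproducible.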

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

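The tests of explanations for the high ADAR0 levels and for the lower FM7a levels, and the intervals over genes, were chosen after the results were seen. The comparisons by mRNA pool and by nascent set were planned, and their use against an explanation was not. At 6 named sites the mRNA pools of yw and Canton S lay on opposite sides of both nascent sets, and the difference was not tested. The yw level minus the Canton S level was 55 points at Pde1c, 19 points at tim (position 3503636), 35 points at bt, 36 points at oc, -12 points at Rya-r44F and -33 points at Cpn. The sites of oc and Cpn were named after their values were seen. Of the 257 sites, 42 (16.3%) showed such opposite placement. Chance ordering would give 16.7% only with equal spreads, no ties and no shift between the RNA classes. The SD of a level was 9.71 points between the mRNA pools and 4.94 points between the nascent sets. The nearness of these shares therefore does not show that the placement is chance.

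High levels in ADAR0 were seen at 8 sites. A strain variant shared with FM7a is a candidate explanation for the 7 sites off the X chromosome, since FM7a was at 50% or more at 7 of 7, against 10% of all sites, while the genomic DNA was from yw. The X-linked site, in norpA, was at 100% in ADAR0 and 0% in FM7a, which argues against a variant shared with FM7a there. A variant of the ADAR0 strain alone or few reads stays open for this site. Editing without ADAR would also appear in yw males, whose highest level at the 8 sites was 31%. They were at 26% at CG16791, 27% at dysc and 31% at sky, so editing without ADAR is not excluded there. At the rest of the 8 sites their highest level was 4%, at CG15431. Reads of control flies, in the share these levels would need, are argued against by a median ADAR0 level of 0% at the 37 sites of 80% or more in nascent RNA. Of these, 24 were listed at 0 and the highest was 20%, at nAcRbeta-64B, so a low share of such reads stays open.

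The higher mRNA levels were seen with mRNA of the same strain, at a median of 8 points for yw (95% interval over genes 6 to 11). The strain of the Canton S mRNA alone would not raise yw mRNA, but a choice of sites by their yw mRNA level could. The lowest level at the 257 sites was 12% in yw mRNA and 3% in Canton S mRNA, and how the sites were chosen is not given. The yw excess therefore cannot decide whether strain matters. The interval holds no library error, because the yw mRNA level is 1 pool of 2 libraries. Against the nascent sets taken singly the medians were 4 and 6.5 points, so 1 set did not make the difference. How the sites with an mRNA level were chosen cannot be told apart from a difference between the RNA classes, because the other 1093 sites carry no mRNA level; the Canton S median over the sites given was 3 points. A gain of editing after transcription may contribute and stays open, as does a difference in library preparation.

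The FM7a level also lay below the yw level when sites at 0 in either strain were left out, with a median of 2 points over 1008 sites, which argues against sites listed at 0 in FM7a as the whole cause. At the 127 sites of 60% or more in nascent RNA the median was 4 points (95% interval over genes 0.5 to 7), but these sites were picked by their level in yw, so the finding of sites in yw flies stays open. A strain difference and a difference between the pooled libraries stay open and may both contribute, since each strain has 1 pooled level.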

How the results depend on the processing

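The alternatives chosen after seeing the data were the log2 statistic, those without a list's leading gene, without the 10 genes with the most sites, without X-linked sites, without sites at 50% or more in ADAR0, at 0 in either male strain or with an mRNA level, and those limited to sites seen in all control male libraries or at 50% or more in nascent RNA. No paired analysis was possible because the male columns pool their replicates and the mRNA columns carry no replicate numbers. Coverage minimums, leaving out male replicates, every alternative for time of day and the feature comparison in mRNA gave no value. The limits to sites above 0 and to exons kept all 257 sites, so their 8 values could not move. Of the other 82 alternative values, 67 kept their direction and call or size. This tally does not measure robustness. Most of the list values in it are tests that did not pass and stayed so, at the low power given above. The size limits for the mRNA comparison were 1.77 points for the median and 7.98 percentage points for the share of sites. Both came from the 2 nascent sets, whose own values they also judged. The median mRNA minus nascent difference was 8 points with yw mRNA and 3 with Canton S mRNA, and 4 to 6.5 points without 1 nascent set. The share of sites higher in mRNA was 61.87% with Canton S mRNA and 63.81% to 75.1% without 1 nascent set, against 72.37%. ADAR0 minus FM7a was -11 points in the median and -15 with yw males as the control. At the 609 sites seen in all control male libraries it was -21, with 7 sites higher and 599 lower, and yw minus FM7a was 3 points, with 387 higher and 190 lower; this filter picks sites by being seen in yw and FM7a, so fewer sites and a larger ADAR0 deficit follow by construction. The exon minus intron difference turned to -2 points without the sites that have an mRNA level, which are all exonic. Without PMCA, ATPases and ion pumps had 3 sites per gene, and without rdgA phototransduction had 2, both below the mean of the other edited genes; the median level of phototransduction without rdgA was 9.5% (adjusted p = 0.041 by permutation, with adjusted p from 0.11 to 0.57 under the planned settings). The phototransduction sites left without rdgA include the norpA site at 100% in ADAR0. Unknown RNA depth limits every single-site level.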

Other observations

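Sites on the heterochromatic and unplaced scaffolds numbered 101, of which 99 were intronic. Chromosome 4 held 124 sites in 15 gene entries, 105 of them intronic. At 9 sites the nascent level was 30% or more while both yw and FM7a males were listed at 0. They included adjacent intronic sites of nAcRalpha-30D at 54% and 77% (chromosome 2L, positions 9800125 and 9800126) and exonic sites of oc at 45% and Cpn at 36%. These sites were chosen after their values were seen, and the male read depth is unknown. Over 1346 sites the light:dark nascent level was above the level of yw males at 947 and below it at 353, although both come from yw flies. The male libraries were sequenced on another instrument model, per the labels, and 2 libraries were pooled against 12. Per the labels and file headers they were also small preparations of 40 to 45 heads, of males only. No time of day is listed for them, while the light:dark pool spans 6 times. The lowest light:dark nascent level of a listed site was 4%, whereas 163 sites were listed at 0 in yw males. A choice of sites by their light:dark level would give this direction and stays open.

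A test chosen after the levels were seen asked whether neighbouring sites of a gene have more similar levels than its other sites. The 78 pairs 1 bp apart differed by 19 points in the median, against 16.5 when levels were shuffled within genes (two-sided permutation p = 0.37). The 281 pairs from 2 to 50 bp apart differed by 11 points, against 13 when shuffled (p = 0.1 by permutation). Neither passed the threshold, so a relation of level to distance was not detected and is not excluded.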
